A study of Homo sapiens with 21 samples.

How the data were processed

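RNA was measured in 21 libraries of H9 cells carrying the inducible GSX2 transgene: day 10, and Dox and NoDox at 12, 24 and 48 h, in 7 groups of 3. The groups come from the labels. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples. No group had doxycycline without the transgene, so the drug and the transgene act together in every Dox comparison.

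The deposited counts are whole reads per gene on hg38, made by the authors with tools that include STAR 2.7.9 and Subread 2.0.3 per the submitters' processing notes. The gene annotation and the strand setting are not given in the sources used here. The deposited signal values are normalized counts, which the values show to be the count over 1 factor per sample. DESeq2, with no version, is among the tools that the authors name. The normalized table lists 19874 features, those with at least 10 counts in at least 3 samples. It was used in an alternative, as log2 of the deposited normalized count + 1.

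Genes were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test with robust fitting and Benjamini-Hochberg adjustment over all genes tested, at adjusted p below 0.05. Scaling was by TMM and the filter was filterByExpr, which left 19655 features. The fit held all 7 groups, with 14 residual degrees of freedom and a biological coefficient of variation of 7.24%. There were 9 comparisons: Dox against NoDox at each time, NoDox at each time against day 10, and the differences of the Dox effect between times. The ± of a log2 fold change is its absolute value over the square root of the F statistic, an approximate standard error. It is rough for genes with few reads in a group. For the transgene it was 0.30 at 12 h and 0.38 at 24 h, but 1.30 for the difference of these effects.

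Total counts ran from 14.4 to 33.8 M per library. The floor for a gene with 0 reads was 3 counts, and floors cover counting error only. Where all libraries of a group had 0 reads, the fold is a bound from 3 counts over the group.

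The gene lists, comparisons, tests and the rule for named genes were written before the data were examined. The 31 lists hold 23 test lists and 8 lists of markers of other cells, with 527 members, of which 467 were tested; FGF15 was not in the count table under that name. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over lists within a comparison. An estimated correlation and fry were alternatives. Counts of list members are over all genes tested, and also adjusted over the list alone.

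GSX2 was named first. For each Dox comparison the rule took the 10 genes with the largest increase and the 10 with the largest decrease past the threshold. These needed a mean of at least 2 CPM, replicates wholly apart between groups and no clone-style name. For each uninduced comparison and each difference it took 5 and 5, without the replicate condition for differences. Of each list it took up to 4 members with the largest change, and other list members may be named with their values. Some genes that this rule takes are not reported here.

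Replicate numbers were checked as pairs by correlating the residuals of Dox and NoDox samples of the same number. All 3 correlations were above 0.1 at 24 h (0.243, 0.112 and 0.107) and at no other time of the Dox comparisons. Alternatives were DESeq2 size factors, DESeq2 1.42.0 with its Wald test, no filter, the deposited normalized values, only the groups compared, a replicate block, a test against a log2 fold change of 1, and each replicate left out. Scaling by library totals only, and counts by abundance without the 12 h Dox replicate 3, were chosen after seeing the data.

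The procedure was tested on simulated data with 100 changed genes at each of the log2 fold changes 1 and 2. At a log2 fold change of 1 it recovered 86% for the 12 h Dox effect and 75% for the difference between 24 h and 12 h. At 2 it recovered 100% and 97%. It made 11 and 16 false calls among 19159 genes, and 5 of 200 random lists had p below 0.05. The simulated genes were drawn independently and few were changed. The simulation therefore tests neither the scaling nor the correlation between genes in the real data.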

Results

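RNA was sequenced from human H9 embryonic stem cells carrying a doxycycline-inducible transgene for FLAG-tagged wild-type GSX2, a homeobox regulator of the lateral ganglionic eminence (LGE), the embryonic source of striatal neurons. The cells were differentiated toward an LGE-like fate. Cultures were collected at day 10, and then 12, 24 and 48 h later with doxycycline (Dox) or without it (NoDox). The labels give 100 ng/mL doxycycline for 12 h from day 10, so the 24 h and 48 h samples follow its withdrawal. The 21 libraries form 7 groups of 3, and total counts ran from 14.4 to 33.8 M per library. In the library of 14.4 M, a gene with 0 counts could lie as high as 0.211 CPM (counts scaled to library size), from 3 counts and for counting error only.

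Of the features in the count table, 19655 were tested, with 99.92% of the counts. The first 3 principal components held 39.5%, 17.7% and 9.3% of the variance. Replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of 1.87 to 28.0. The 12 h Dox replicate 3 stood apart from its group, with values of 28.0 and 17.5 against the other replicates. Day 10 replicate 1 did too, with values of 11.5 and 15.6. Fold changes are log2 values ± an approximate standard error with n = 3 per group, and CPM values are means ± SD (n = 3).

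GSX2 itself (chromosome 4, 54099523 to 54102498, hg38) and its transgene set the timing of the series. The transgene was listed at 0.309 ± 0.0436 CPM at day 10 and stayed between 0.135 and 0.279 CPM in the NoDox groups. It reached 876 ± 114 CPM at 12 h of doxycycline. It was at 19.5 ± 5.80 CPM at 24 h and 0.934 CPM at 48 h. Reads counted for GSX2 rose at 12 h, 288 ± 9.73 against 8.62 ± 1.80 CPM, a log2 fold change of 5.07 ± 0.20 (adjusted p = 9.7e-13). At 24 h they were below the uninduced level, 6.28 ± 2.73 against 12.7 ± 1.77 CPM (-1.04 ± 0.22, adjusted p = 0.00147), and at 48 h also, 1.96 ± 0.0609 against 11.1 ± 1.92 CPM (-2.49 ± 0.31, adjusted p = 2.26e-05). The ratio of GSX2 reads to transgene reads was 0.333 ± 0.0567 at 12 h and 0.315 ± 0.0478 at 24 h of the Dox series. Any transgene reads counted for GSX2 were not separated from those of the resident gene. The values therefore give no order of the resident gene's level among the Dox times. Such reads could only add to the count, so the resident gene was also below its NoDox level at 24 h and 48 h.

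**Figure D1:**
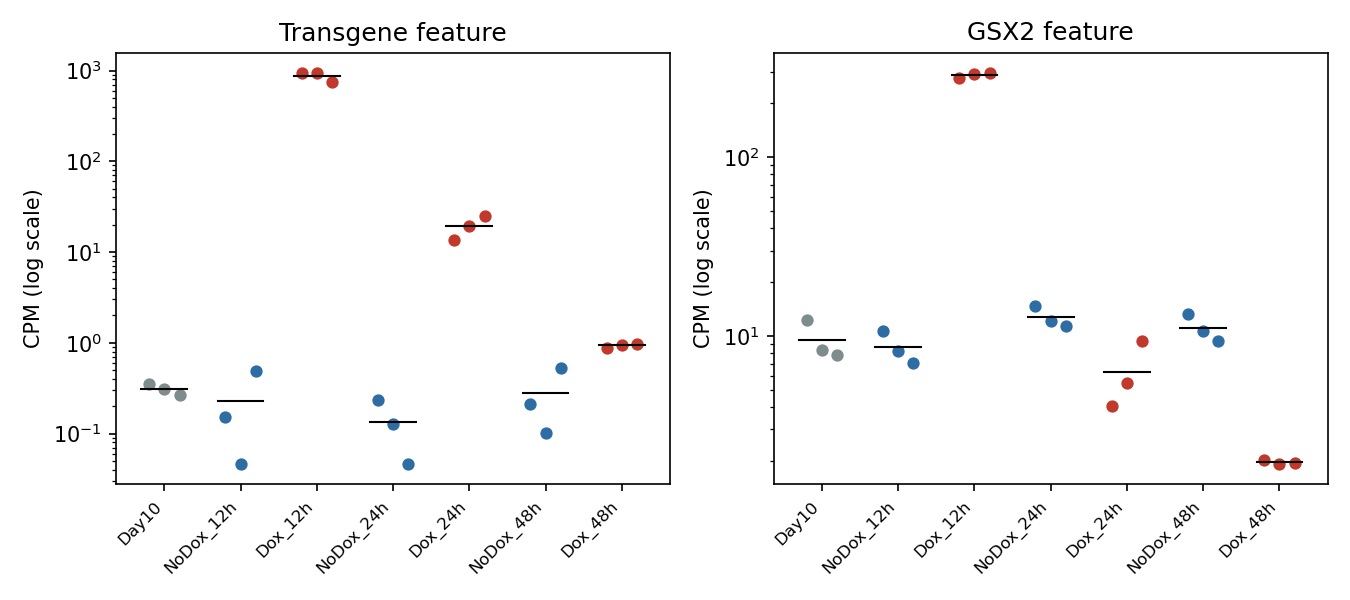
CPM of the transgene feature (left) and of GSX2 (right) in each library on log axes, with the group mean as a line; libraries with 0 reads would not be drawn. The transgene averaged 876 CPM in the 12 h Dox libraries and 0.934 CPM in the 48 h Dox libraries.

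The first comparison asked what GSX2 induction had changed after 12 h of doxycycline. Regulators of the dorsal telencephalon fell steeply. EMX2, a transcription factor of the cortical primordium, went from 247 ± 20.1 to 9.54 ± 0.764 CPM in the Dox libraries (log2 fold change -4.70 ± 0.11, adjusted p = 6.75e-22). EOMES, which marks intermediate progenitors of the cortex, fell from 67.9 ± 13.1 CPM (-5.47 ± 0.17), and the proneural factor NEUROG1 fell from 21.7 ± 1.70 to 0.465 ± 0.233 CPM (-5.46 ± 0.20). The neural stem cell factor SOX2 fell from 838 to 135 CPM (-2.63 ± 0.08, adjusted p = 1.06e-21). In all, 3898 genes were higher and 3912 lower with doxycycline, 1092 and 930 of them by at least 2-fold.

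Among other genes with a mean of at least 2 CPM and replicates wholly apart, the rule for named genes took for their decreases PCDH8, a protocadherin (-5.93 ± 0.52), EDNRB, the endothelin B receptor (-5.33 ± 0.13), and the homeobox gene UNCX (-5.23 ± 0.22). NXPH1, a secreted glycoprotein gene (-5.07 ± 0.39), RSPO3, which amplifies WNT signals (-4.93 ± 0.23), and SOX21 (-4.66 ± 0.11) fell as well. The genes it took for their increases after the transgene and GSX2 changed less than these and were of low abundance. NGEF rose from 0.448 ± 0.0961 to 4.77 ± 0.447 CPM (3.39 ± 0.24). ALS2CL (2.97 ± 0.24), the T-type calcium channel CACNA1I (2.96 ± 0.25) and the transglutaminase TGM2 (2.84 ± 0.22) rose too. So did HSPA12B (2.71 ± 0.20), CCDC69 (2.62 ± 0.21), the PACAP receptor ADCYAP1R1 (2.58 ± 0.22) and TESMIN (2.52 ± 0.23). TESMIN stood at 4.10 ± 0.114 CPM at day 10, 0.609 ± 0.273 in NoDox and 3.60 ± 0.356 in Dox at 12 h. CACNA1I stood at 3.24 ± 0.161, 0.778 ± 0.323 and 6.07 ± 1.69 CPM in the same groups. Dox was not compared with day 10.

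Patterning lists moved down together at 12 h. Of the dorsal pallial regulators, 0 of 20 tested rose and 17 fell (0 and 17 adjusted over the list alone), with a median of -2.68 and adjusted p = 2.25e-16. LHX9 (-3.94 ± 0.25) and TFAP2C (-3.91 ± 0.38) were among them beside EOMES, NEUROG1 and EMX2. Of the LGE progenitor regulators, 1 of 14 tested rose and 11 fell (1 and 11 adjusted over the list alone), with a median of -1.59 and adjusted p = 2.16e-07. The 1 that rose was GSX2 itself, which is counted in this list in every comparison. GSX1, the closest relative of GSX2, had 0 reads in the 12 h Dox libraries against 1.41 ± 0.250 CPM, at least 34.6-fold lower by a floor of 3 counts over the group, and the list median is the same with it at that bound. MEIS1 fell too (-2.31 ± 0.13). Of the GABAergic and striatal neuron genes, 2 of 25 tested rose and 19 fell (3 and 19 adjusted over the list alone), with a median of -0.96 and adjusted p = 4.94e-06. ISL1 (-4.21 ± 0.29), DLX6-AS1 (-3.00 ± 0.52) and DLX6 (-2.63 ± 0.32) fell. In the LGE list DLX1 fell (-0.64 ± 0.23, adjusted p = 0.0392) and DLX2 did not pass (-0.45 ± 0.29, adjusted p = 0.235). Of the ventral pallium and pallial-subpallial boundary genes, 0 of 11 tested rose and 9 fell (0 and 9 adjusted over the list alone), with a median of -1.07 and adjusted p = 3.77e-05. DBX1 (-5.34 ± 0.72), FGF7 (-4.20 ± 0.67) and BARHL2 (-3.99 ± 0.87) were among those that fell. MGE and ventral midline genes did not pass as a list (1 up, 4 down of 9, median -0.97, adjusted p = 0.0981), though NKX2-1, which specifies the medial ganglionic eminence (MGE), fell (-3.74 ± 0.52).

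Progenitor and neurogenesis genes fell at 12 h as well. The radial glia, neurogenesis, Notch and dorsal pallial lists share members, among them NEUROG2, PAX6 and HES6, so their results are not independent. Of the radial glia and neural progenitor genes, 0 of 22 tested rose and 20 fell (0 and 21 adjusted over the list alone), with a median of -1.13 and adjusted p = 8.35e-22. SOX2 is in this list, and PAX6 fell by about as much (-2.39 ± 0.07). Of the neurogenesis-initiating genes, 2 of 28 tested rose and 25 fell (2 and 25 adjusted over the list alone), with a median of -1.46 and adjusted p = 7.2e-18. INSM1 (-3.00 ± 0.10) and NEUROG2 (-3.55 ± 0.64) were examples. Of the Notch pathway genes, 3 of 21 tested rose and 15 fell (3 and 15 adjusted over the list alone), with a median of -0.74 and adjusted p = 1.92e-07. HES6 (-2.14 ± 0.07) and the ligand JAG1 (-1.76 ± 0.09) fell, and the ligand JAG2 rose (1.33 ± 0.09). Of the postmitotic neuron genes, 3 of 24 tested rose and 16 fell (3 and 17 adjusted over the list alone), with a median of -0.57 and adjusted p = 3.13e-05 (adjusted p = 0.278 with an estimated correlation). SYT4 (-2.17 ± 0.11) and GAP43 (-1.15 ± 0.15) fell and MAPT, which encodes tau, rose (0.85 ± 0.13). Of the ephrin, semaphorin and guidance genes, 3 of 29 tested rose and 23 fell (3 and 23 adjusted over the list alone), with a median of -1.09 and adjusted p = 3.64e-13. SLIT2 (-2.92 ± 0.11) and NRP1 (-2.55 ± 0.23) were examples.

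Signalling and cell cycle lists followed the same direction at 12 h. Of the WNT pathway genes, 4 of 27 tested rose and 16 fell (5 and 17 adjusted over the list alone), with a median of -0.73 and adjusted p = 9.89e-07, with the receptor FZD5 (-3.83 ± 0.18) and LGR5 (-3.25 ± 0.15) among those that fell. Of the FGF pathway genes, 1 of 21 tested rose and 14 fell (1 and 14 adjusted over the list alone), with a median of -0.60 and adjusted p = 4.44e-07. DUSP6, a feedback phosphatase of ERK, fell from 43.5 ± 6.07 to 7.13 ± 1.24 CPM (-2.62 ± 0.12), and FGF19 fell more steeply (-5.51 ± 0.55). Of the BMP and TGF-beta pathway genes, 4 of 23 tested rose and 9 fell (6 and 9 adjusted over the list alone), with a median of -0.17 and adjusted p = 0.0239 (adjusted p = 0.0609 with an estimated correlation). This list held TGFB2 (-3.53 ± 0.14), FST (-2.60 ± 0.08) and NOG (-2.52 ± 0.10), the latter pair encoding antagonists. With library totals as the only scaling its median was 0.01, and its test still went down. Of the S phase and G1 cyclin genes, 1 of 22 tested rose and 19 fell (1 and 19 adjusted over the list alone), with a median of -0.55 and adjusted p = 8.7e-10, with MCM7 (-1.01 ± 0.06) and E2F1 (-0.94 ± 0.08) lower. Of the G2 and M phase genes, 0 of 23 tested rose and 5 fell (0 and 4 adjusted over the list alone), with a median of -0.14 and adjusted p = 0.0245 (adjusted p = 0.516 with an estimated correlation), and with library totals only this median was 0.04 and the call was lost (adjusted p = 0.296). Of the cell cycle inhibitors, 1 of 11 tested rose and 8 fell (1 and 8 adjusted over the list alone), with a median of -0.58 and adjusted p = 2.81e-05, including CDKN2B (-3.17 ± 0.18) and CDKN1C (-1.51 ± 0.09).

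Of the immediate early genes, 1 of 12 tested rose and 11 fell (1 and 11 adjusted over the list alone), with a median of -0.92 and adjusted p = 1.53e-06 (adjusted p = 0.0589 with an estimated correlation), with EGR3 (-2.30 ± 0.31) and FOSB (-1.71 ± 0.25) lower. Of the hypoxia and glycolysis genes, 1 of 21 tested rose and 12 fell (1 and 12 adjusted over the list alone), with a median of -0.29 and adjusted p = 2.51e-04 (adjusted p = 0.165 with an estimated correlation). The glucose transporters SLC2A3 (-1.04 ± 0.07) and SLC2A1 (-0.90 ± 0.08) fell. The ATF4 stress response list went up: 10 of 20 tested rose and 4 fell (12 and 4 adjusted over the list alone), with a median of 0.21 and adjusted p = 0.0306 (adjusted p = 0.330 with an estimated correlation). CHAC1 (1.21 ± 0.15), CEBPB (1.15 ± 0.12) and ASNS (0.83 ± 0.10) rose, while DDIT4 fell (-1.45 ± 0.09). Retinoic acid pathway genes did not pass (4 up, 3 down of 13, median 0.19, adjusted p = 0.741); their mean was -0.07, and their test pointed up with TMM and down with library totals only. Mitochondrially encoded protein genes, which doxycycline can affect through mitochondrial translation, did not pass (0 up, 0 down of 13, median -0.08, adjusted p = 0.243), and their median was 0.10 with library totals only.

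Markers of other cells were mostly lower or mixed at 12 h. Of the diencephalon, hypothalamus and eye field markers, 1 of 13 tested rose and 11 fell (1 and 11 adjusted over the list alone), with a median of -1.55 and adjusted p = 1.25e-06, with OTX2 lower (-1.78 ± 0.06). Of the cortical hem, roof plate and choroid plexus markers, 3 of 12 tested rose and 8 fell (4 and 8 adjusted over the list alone), with a median of -1.28 and adjusted p = 8.44e-04, with ZIC4 lower (-2.09 ± 0.09) and LMX1B higher (2.85 ± 0.54). Of the midbrain and hindbrain markers, 0 of 6 tested rose and 3 fell (0 and 4 adjusted over the list alone), with a median of -1.13 and adjusted p = 0.0306 (adjusted p = 0.190 with an estimated correlation), with IRX1 at -2.19 ± 0.19. Neural crest markers (3 up, 2 down of 7, median 0.15, adjusted p = 0.901) and oligodendrocyte lineage genes (2 up, 4 down of 11, median -0.39, adjusted p = 0.279) did not pass, although the nerve growth factor receptor NGFR rose (1.84 ± 0.10). Astrocyte genes (2 up, 4 down of 9, median -0.35, adjusted p = 0.279) did not pass, and GFAP rose (3.03 ± 0.34). Pluripotent stem cell markers (2 up, 3 down of 7, median -0.16, adjusted p = 0.375) had a mean of 0.07 against a negative median and test. Mesoderm and endoderm markers (2 up, 1 down of 6, median 0.66, adjusted p = 0.250), non-neural ectoderm and epithelial markers (2 up, 2 down of 8, median 0.57, adjusted p = 0.219) and mesenchymal and endothelial markers (3 up, 4 down of 10, median -0.26, adjusted p = 0.170) did not pass. The test of the neural crest list pointed down with library totals only, and the median of the pluripotent list was then 0.02. The MGE list (adjusted p = 0.0194) and the mesenchymal and endothelial list (adjusted p = 0.0425) went down past the threshold with library totals only.

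The size of the increases at 12 h rested on the scaling. TMM factors were 1.12 to 1.14 in the 12 h Dox libraries, and 0.891 to 1.02 in the rest. With library totals as the only scaling, 7340 genes were higher and 2213 lower, and the median of all genes moved by 0.18. Features too low to test held 974, 976 and 1324 reads per M in the 12 h Dox replicates 1, 2 and 3, against 641 to 819.6 in the other 18 libraries. Without replicate 3, 3782 genes were higher and 3987 lower.

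The second comparison asked what remained, or had newly changed, at 24 h, 12 h after doxycycline was withdrawn. Dorsal regulators were still low, and FGF pathway genes were now high. EMX2 stood at 20.4 ± 4.14 against 314 ± 11.6 CPM (-3.94 ± 0.10, adjusted p = 2.8e-20). DUSP6 was at 80.8 ± 6.52 against 12.8 ± 1.60 CPM (2.66 ± 0.11, adjusted p = 1.82e-17), and FGF8, a morphogen of the anterior forebrain, was at 61.2 ± 1.74 against 7.04 ± 1.05 CPM (3.13 ± 0.12). SOX2 was lower by far less than at 12 h (-0.20 ± 0.07, adjusted p = 0.0292). In all, 3349 genes were higher and 3316 lower, 726 and 680 of them by at least 2-fold.

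CER1, a secreted antagonist of BMP, Nodal and WNT, showed the largest increase after the transgene at 24 h among the genes named by rule (6.10 ± 0.32). SELE, which encodes E-selectin, rose from 0.328 ± 0.104 to 19.0 ± 4.75 CPM (5.80 ± 0.38), and KDR, the main VEGF receptor, rose from 2.08 ± 0.342 to 37.9 ± 4.58 CPM (4.21 ± 0.23). FAM181B (3.85 ± 0.18), the lysophosphatidic acid receptor LPAR1 (3.80 ± 0.12), RASL12 (3.42 ± 0.18), the morphogen BMP2 (3.24 ± 0.10), GRHL3 (3.20 ± 0.24) and the guidance ligand SLIT3 (3.19 ± 0.15) also rose. Taken by the same rule for their decreases were PCDH20, a protocadherin (-6.40 ± 0.38), FSTL5 (-4.77 ± 0.22), GPR149 (-4.58 ± 0.32) and PCSK1, a prohormone convertase (-4.55 ± 0.18). The cannabinoid receptor CNR1 (-4.52 ± 0.24), RASGRP1 (-4.29 ± 0.12), CCSER1 (-4.19 ± 0.25), ARHGAP36 (-4.12 ± 0.27) and EMX2OS, the antisense transcript of EMX2 (-3.96 ± 0.11), fell with them.

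Of the FGF pathway genes at 24 h, 13 of 21 tested rose and 3 fell (14 and 5 adjusted over the list alone), with a median of 0.66 and adjusted p = 1.13e-08. ETV4 (3.18 ± 0.13), an ERK-responsive transcription factor, and SPRY4 (3.15 ± 0.21), a feedback inhibitor, rose with FGF8 and DUSP6, and FGF19 fell (-2.91 ± 0.44). The uninduced cultures moved the other way over these hours, since FGF8 went from 19.3 CPM at day 10 to 7.04 CPM at 24 h. Of the BMP and TGF-beta pathway genes, 11 of 23 tested rose and 6 fell (11 and 6 adjusted over the list alone), with a median of 0.31 and adjusted p = 0.0437 (adjusted p = 0.143 with an estimated correlation). BMP2, LEFTY1 (3.08 ± 0.63) and ID2 (1.90 ± 0.10) rose, and BMP5 fell (-2.92 ± 0.62). Of the hypoxia and glycolysis genes, 8 of 21 tested rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.12 and adjusted p = 0.0389 (adjusted p = 0.482 with an estimated correlation), with SLC2A1 (1.16 ± 0.08) and ADM (0.77 ± 0.20) higher. WNT pathway genes did not pass (9 up, 6 down of 27, median 0.17, adjusted p = 0.835). Their mean was -0.14, the opposite sign to their median. Notch pathway genes did not pass as a list (11 up, 8 down of 21, median 0.23, adjusted p = 0.414), but HEY1, a Notch target, rose from 24.7 ± 1.32 to 144 ± 6.85 CPM (2.54 ± 0.08).

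Neuronal lists were lower than in NoDox at 24 h. The postmitotic, neurogenesis-initiating and GABAergic lists went up in NoDox from day 10 to 24 h. Their fall against NoDox therefore includes a rise of the control. Of the dorsal pallial regulators, 3 of 20 tested rose and 15 fell (3 and 15 adjusted over the list alone), with a median of -1.37 and adjusted p = 7.91e-08, with LHX9 (-3.52 ± 0.25) and EOMES (-3.30 ± 0.13) lower. Of the postmitotic neuron genes, 2 of 24 tested rose and 20 fell (2 and 20 adjusted over the list alone), with a median of -0.61 and adjusted p = 7.76e-10 (adjusted p = 0.165 with an estimated correlation), with SYT4 lower (-1.58 ± 0.11). Of the neurogenesis-initiating genes, 2 of 28 tested rose and 16 fell (2 and 16 adjusted over the list alone), with a median of -0.39 and adjusted p = 1.06e-06 (adjusted p = 0.126 with an estimated correlation), with NEUROG1 (-2.86 ± 0.16) and POU3F2 (-1.27 ± 0.17) lower. Of the GABAergic and striatal neuron genes, 4 of 25 tested rose and 12 fell (5 and 13 adjusted over the list alone), with a median of -0.42 and adjusted p = 0.0132 (adjusted p = 0.316 with an estimated correlation), with ERBB4 lower (-3.59 ± 0.17) and ARPP21 higher (2.01 ± 0.34). LGE progenitor regulators did not pass as a list (4 up, 7 down of 14, median -0.30, adjusted p = 0.414). In that list VAX1 (2.23 ± 0.10) and DLX1 (1.20 ± 0.21) rose and MEIS1 fell (-2.13 ± 0.12). Of the immediate early genes, 0 of 12 tested rose and 9 fell (0 and 9 adjusted over the list alone), with a median of -0.57 and adjusted p = 2.62e-04 (adjusted p = 0.198 with an estimated correlation), with NR4A1 lower (-1.04 ± 0.08). Of the cell cycle inhibitors, 0 of 11 tested rose and 8 fell (0 and 8 adjusted over the list alone), with a median of -0.47 and adjusted p = 2.62e-04 (adjusted p = 0.0644 with an estimated correlation), with CDKN2C lower (-2.21 ± 0.18). Radial glia and neural progenitor genes no longer passed (6 up, 9 down of 22, median -0.12, adjusted p = 0.174).

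Markers of neural crest and of epithelium were higher at 24 h. Of the neural crest markers, 7 of 7 tested rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.18 and adjusted p = 2.13e-05. SOX10 (1.90 ± 0.14), PAX7 (1.87 ± 0.27) and ETS1 (1.40 ± 0.21) were among them. FOXD3, TWIST1, TFAP2B and PAX3 of this list were too low to test, with 16, 20, 52 and 99 reads over all libraries. The list went down in NoDox from day 10 to 24 h, so its rise over NoDox includes a fall of the control. SOX10 is also in the oligodendrocyte list, which shares 2 members with the neural crest list. Of the oligodendrocyte list, 6 of 11 tested rose and 3 fell (6 and 3 adjusted over the list alone), with a median of 0.60 and adjusted p = 0.0457 (adjusted p = 0.159 with an estimated correlation). Of the non-neural ectoderm and epithelial markers, 5 of 8 tested rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 1.06 and adjusted p = 0.00142 (adjusted p = 0.0644 with an estimated correlation), with the keratin KRT18 (1.69 ± 0.11) beside GRHL3. Of the pluripotent stem cell markers, which did not pass as a list (4 up, 1 down of 7, median 0.22, adjusted p = 0.107), the RNA-binding protein gene L1TD1 rose from 7.76 ± 0.538 to 63.9 ± 3.35 CPM (3.05 ± 0.12). DNMT3B passed by little (0.24 ± 0.09, adjusted p = 0.0450) and did not with replicate number as a block. Mitochondrially encoded protein genes did not pass (3 up, 0 down of 13, median 0.15, adjusted p = 0.0586) and did with the block (adjusted p = 0.0424).

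**Figure D2:**
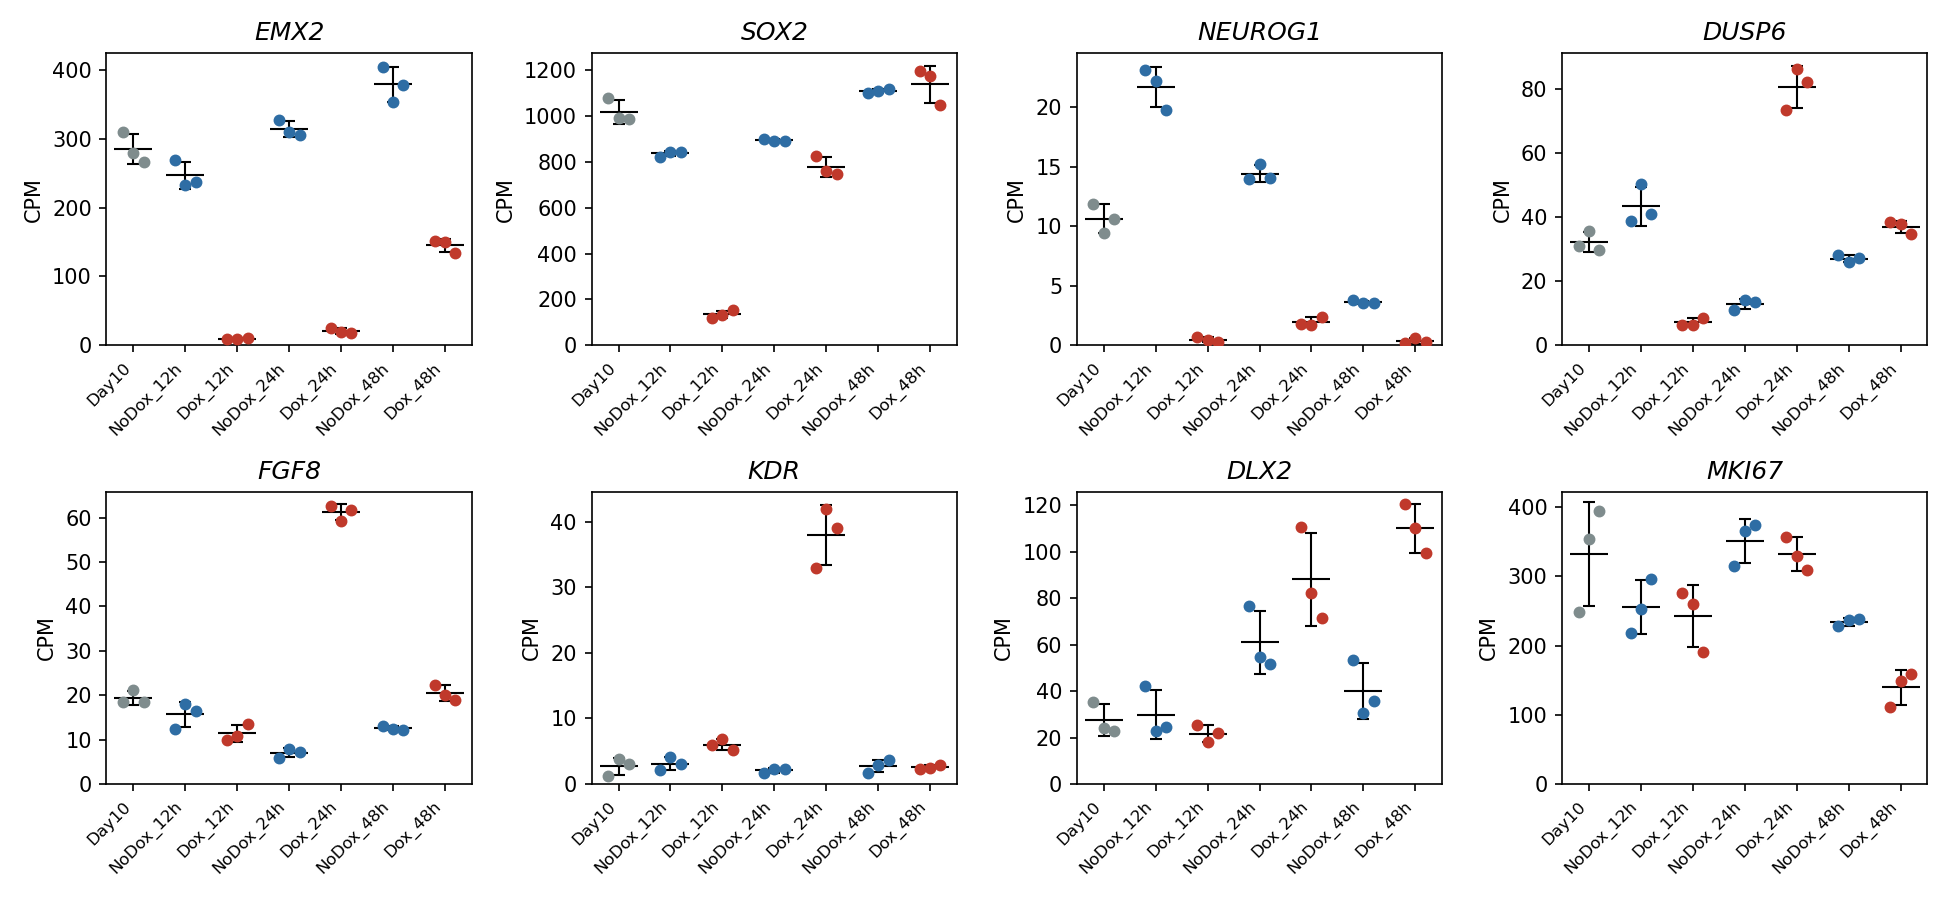
CPM of 8 genes in each library by group, with the mean and SD as a line and bars (n = 3). EMX2 averaged 20.4 CPM in the 24 h Dox group against 314 CPM without doxycycline, and DUSP6 80.8 against 12.8 CPM.

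The third comparison asked what persisted at 48 h. G2 and M phase genes were lower, some dorsal regulators were still low, and DLX1 and DLX2, regulators of the ventral telencephalon, were higher. All 23 G2 and M phase genes tested fell; the motility receptor HMMR went from 44.8 ± 1.27 to 23.5 ± 1.000 CPM (-0.93 ± 0.07) and cyclin B1, CCNB1, from 199 ± 6.41 to 109.7 ± 6.50 CPM (-0.86 ± 0.08). DLX2, which drives GABAergic differentiation, rose from 39.9 ± 12.0 to 110.1 ± 10.6 CPM (1.47 ± 0.27, adjusted p = 0.00138), and DLX1 rose too (1.21 ± 0.23, adjusted p = 0.00156). EMX2 was at 145 ± 9.70 against 379 ± 25.5 CPM (-1.38 ± 0.09). In all, 1814 genes were higher and 1757 lower, 144 and 235 of them by at least 2-fold.

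CER1 (4.67 ± 0.74) and SELE (3.74 ± 0.65) had the largest increases among the genes named by rule, though at 1.03 and 1.90 CPM. GRIP2 (2.26 ± 0.17), SLIT3 (2.19 ± 0.16), SLITRK2 (1.76 ± 0.10), the LIM-only factor LMO1 (1.75 ± 0.09), COL23A1 (1.66 ± 0.29), GRHL3 (1.66 ± 0.29), LPAR1 (1.61 ± 0.13) and MIR9-1HG, the host transcript of a neural microRNA (1.51 ± 0.19), rose. KDR did not pass at 48 h (-0.10 ± 0.31, adjusted p = 0.862). Taken for their decreases beside GSX2 were NEUROG1 (-3.33 ± 0.29), SPINK5 (-3.04 ± 0.24), RASGRP1 (-3.00 ± 0.11) and BRINP2 (-2.91 ± 0.34). The nicotinic receptor subunits CHRNB4 (-2.71 ± 0.28) and CHRNA3 (-2.43 ± 0.16), the glutamate receptor subunit GRIN3A (-2.66 ± 0.22) and POMC (-2.27 ± 0.21) fell with them.

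Among lists at 48 h, the G2 and M phase genes passed with a median of -0.70 (adjusted p = 1.15e-36), all 23 adjusted over the list alone as well. Their call held with an estimated correlation (adjusted p = 0.0418). Of the dorsal pallial regulators, 2 of 20 tested rose and 9 fell (3 and 12 adjusted over the list alone), with a median of -1.19 and adjusted p = 9.45e-05 (adjusted p = 0.238 with an estimated correlation); FEZF2 was among those that rose (0.76 ± 0.08). The other 29 lists did not pass. FGF pathway genes were 9 up, 2 down of 21, median 0.04, adjusted p = 0.0640, with FGFR2 (1.25 ± 0.12) and SPRY4 (1.14 ± 0.19) higher and FGF18 lower (-1.71 ± 0.25); their median was -0.04 with library totals only. Radial glia and neural progenitor genes were 7 up, 0 down of 22, median 0.16, adjusted p = 0.0504, with TNC (0.79 ± 0.21) and FABP7 (0.57 ± 0.13) higher. LGE progenitor regulators were 4 up, 4 down of 14, median 0.16, adjusted p = 0.211 with a mean of -0.04, and GABAergic and striatal neuron genes were 5 up, 2 down of 25, median 0.20, adjusted p = 0.150, with SLC32A1, the vesicular GABA transporter, higher (0.98 ± 0.20).

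With library totals as the only scaling, 1017 genes were higher and 2835 lower at 48 h. The count of higher genes fell to 1041 without NoDox 48 h replicate 2 and to 1056 without Dox 48 h replicate 1.

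**Figure D3:**
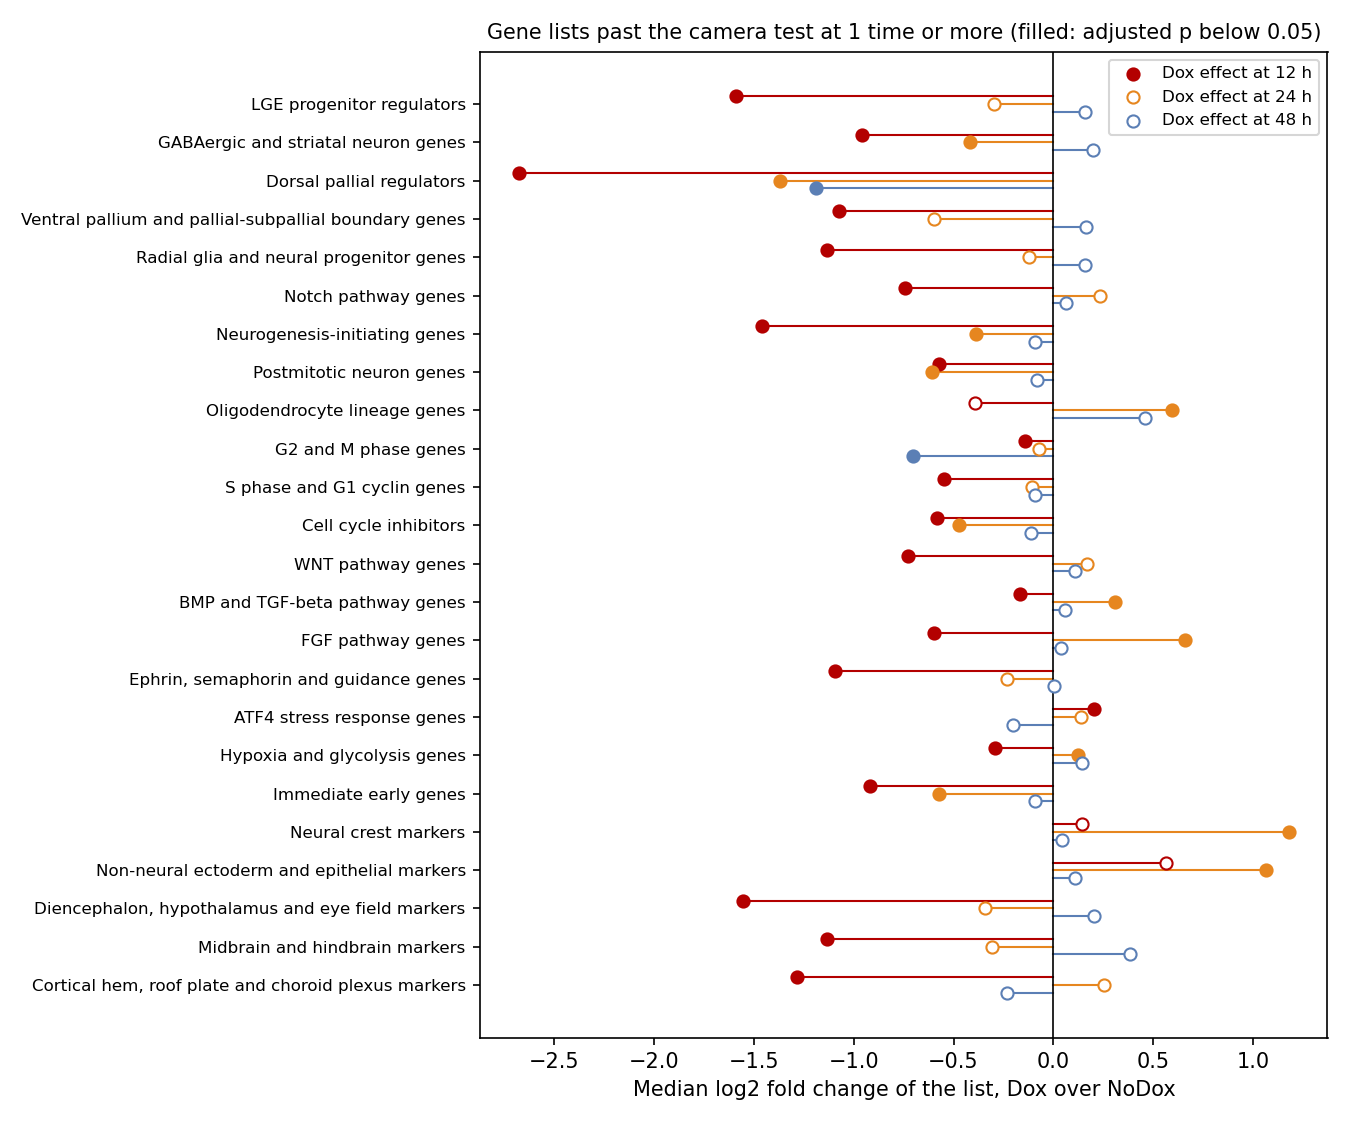
Median log2 fold change, Dox over NoDox, of the gene lists that passed the camera test at 1 time or more, at 12, 24 and 48 h; filled points passed at adjusted p below 0.05. The dorsal pallial list lay at -2.68, -1.37 and -1.19. With library totals only, the medians of the BMP and G2 lists at 12 h and of the Notch, BMP and FGF lists at 48 h changed sign.

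**Figure D4:**
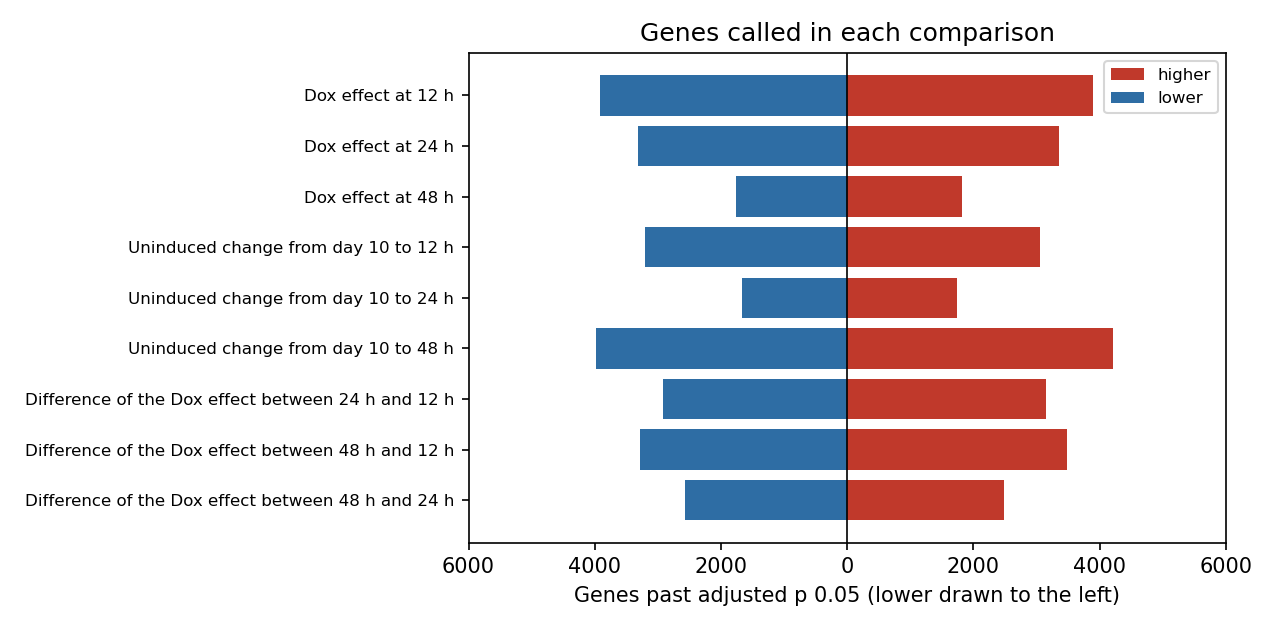
Number of genes called higher (right) and lower (left) in each of the 9 comparisons at adjusted p below 0.05. The first bar holds 3898 and 3912 genes. With library totals only, that split became 7340 and 2213.

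The change of the uninduced cultures over the same hours gives the background of these effects. It was read as NoDox against day 10, with the 3 comparisons sharing the day 10 libraries. Where a list went up in NoDox, a lower value with doxycycline includes a rise of the control. By 12 h this holds for the neurogenesis-initiating, S phase, BMP and hypoxia lists. The course was not steady. On the first principal component the NoDox 12 h libraries lay at 28.8 to 31.4. Those of day 10 lay at -3.53 to 2.76 and those of NoDox 24 h at -7.85 to -2.15. All 21 hypoxia and glycolysis genes tested rose by 24 h and by 48 h. NDRG1, a hypoxia-induced gene, went from 50.3 ± 5.86 to 380.2 ± 7.32 CPM by 48 h (2.92 ± 0.13), and HIF1A-AS3, an antisense transcript at the HIF1A locus, from 0.558 ± 0.127 to 8.21 ± 0.228 CPM (3.91 ± 0.26). GSX2 itself did not pass at 12 h (-0.10 ± 0.23, adjusted p = 0.778), 24 h (0.48 ± 0.22, adjusted p = 0.153) or 48 h (0.26 ± 0.23, adjusted p = 0.381).

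By 12 h without doxycycline, 3051 genes were higher and 3202 lower, 470 and 314 by at least 2-fold. WNT3A, a WNT ligand of the cortical hem, rose from 0.741 ± 0.103 to 9.30 ± 0.904 CPM (3.62 ± 0.22), and SH3RF3 (3.04 ± 0.19), CER1 (2.71 ± 0.56), TMEM132D (2.46 ± 0.37) and HIF1A-AS3 (2.27 ± 0.30) rose. TESMIN (-2.71 ± 0.23), the cell cycle inhibitor CDKN2C (-2.28 ± 0.19), CACNA1I (-2.05 ± 0.27), the corticotropin-releasing hormone receptor CRHR1 (-2.04 ± 0.22) and ATP8B3 (-2.01 ± 0.23) fell. Of the BMP and TGF-beta pathway genes, 11 of 23 tested rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.39 and adjusted p = 6.14e-05, with LEFTY2 higher (2.03 ± 0.12). Of the hypoxia and glycolysis genes, 12 of 21 tested rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.49 and adjusted p = 1.05e-09 (adjusted p = 0.124 with an estimated correlation), with PFKFB3 higher (1.79 ± 0.09). Of the S phase and G1 cyclin genes, 16 of 22 tested rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.36 and adjusted p = 2.32e-06 (adjusted p = 0.262 with an estimated correlation), and of the G2 and M phase genes, 0 of 23 tested rose and 20 fell (0 and 22 adjusted over the list alone), with a median of -0.48 and adjusted p = 1.62e-13 (adjusted p = 0.262 with an estimated correlation). Neurogenesis-initiating genes (13 up, 0 down of 28, median 0.28, adjusted p = 6.14e-05, adjusted p = 0.278 with an estimated correlation) and ATF4 stress response genes (11 up, 0 down of 20, median 0.23, adjusted p = 0.00337, adjusted p = 0.327 with an estimated correlation) went up, and immediate early genes (0 up, 9 down of 12, median -0.58, adjusted p = 1.13e-05, adjusted p = 0.262 with an estimated correlation) went down.

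By 24 h, 1738 genes were higher and 1664 lower, 307 and 110 by at least 2-fold; without NoDox 24 h replicate 1 these counts were 1118 and 945. HIF1A-AS3 (3.42 ± 0.27), NDUFA4L2, a hypoxia-induced mitochondrial protein gene (2.41 ± 0.30), MIR7-3HG (2.38 ± 0.34), the lysyl oxidase LOX (2.31 ± 0.22) and DLX6-AS1 (2.26 ± 0.40) rose. IGFBP3 (-1.97 ± 0.14), ACTN3 (-1.77 ± 0.25), FGF8 (-1.48 ± 0.13), A4GALT (-1.45 ± 0.18) and RASL12 (-1.45 ± 0.22) fell. Of the hypoxia and glycolysis genes, 21 of 21 tested rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.75 and adjusted p = 7.93e-30. Of the mitochondrially encoded protein genes, 0 of 13 tested rose and 9 fell (0 and 9 adjusted over the list alone), with a median of -0.54 and adjusted p = 1.01e-11, with MT-ND6 (-1.12 ± 0.15) and MT-ND1 (-0.90 ± 0.08) lower. Of the FGF pathway genes, 2 of 21 tested rose and 11 fell (4 and 13 adjusted over the list alone), with a median of -0.21 and adjusted p = 1.96e-06. Of the neurogenesis-initiating genes, 17 of 28 tested rose and 1 fell (20 and 2 adjusted over the list alone), with a median of 0.44 and adjusted p = 8.05e-11, and of the postmitotic neuron genes, 16 of 24 tested rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.42 and adjusted p = 8.41e-13 (adjusted p = 0.0976 with an estimated correlation). GABAergic and striatal neuron genes (14 up, 2 down of 25, median 0.61, adjusted p = 1.69e-05, adjusted p = 0.0856 with an estimated correlation) and LGE progenitor regulators (7 up, 2 down of 14, median 0.37, adjusted p = 0.00344, adjusted p = 0.170 with an estimated correlation) went up.

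Lists of other cells and of the cell cycle went down by 24 h without doxycycline. Neural crest markers (0 up, 5 down of 7, median -0.64, adjusted p = 5.65e-04) and pluripotent stem cell markers (0 up, 4 down of 7, median -0.57, adjusted p = 1.96e-05) did, with SOX10 (-1.17 ± 0.15) and ZFP42 (-1.35 ± 0.17) as examples. Midbrain and hindbrain markers (0 up, 4 down of 6, median -0.53, adjusted p = 0.00122, adjusted p = 0.0926 with an estimated correlation) and cortical hem, roof plate and choroid plexus markers (1 up, 4 down of 12, median -0.35, adjusted p = 0.0281, adjusted p = 0.170 with an estimated correlation) did too. So did S phase and G1 cyclin genes (1 up, 8 down of 22, median -0.15, adjusted p = 0.00154, adjusted p = 0.298 with an estimated correlation), G2 and M phase genes (0 up, 4 down of 23, median -0.14, adjusted p = 9.58e-04, adjusted p = 0.415 with an estimated correlation), WNT pathway genes (3 up, 7 down of 27, median -0.24, adjusted p = 0.0444, adjusted p = 0.168 with an estimated correlation) and immediate early genes (0 up, 4 down of 12, median -0.25, adjusted p = 0.00122, adjusted p = 0.243 with an estimated correlation).

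By 48 h, 4215 genes were higher and 3973 lower, 741 and 562 by at least 2-fold, and 3176 and 5174 with library totals only. PTPRB, a receptor phosphatase (2.93 ± 0.18), NDUFA4L2 (3.08 ± 0.30) and the carbonic anhydrase CA9 (2.88 ± 0.29) rose beside HIF1A-AS3 and NDRG1. DIPK1C (-2.09 ± 0.16), F8 (-2.05 ± 0.27), the potassium channel KCNJ13 (-1.97 ± 0.19) and EMX1 (-1.87 ± 0.27) fell. Of the hypoxia and glycolysis genes, 21 of 21 tested rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 1.06 and adjusted p = 7.44e-21. Of the postmitotic neuron genes, 21 of 24 tested rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.66 and adjusted p = 1.99e-09 (adjusted p = 0.220 with an estimated correlation), with GAP43 (1.70 ± 0.14) and L1CAM (1.51 ± 0.09) higher. Of the S phase and G1 cyclin genes, 1 of 22 tested rose and 18 fell (1 and 18 adjusted over the list alone), with a median of -0.60 and adjusted p = 7.58e-12 (adjusted p = 0.0813 with an estimated correlation), with CCNE2 lower (-1.48 ± 0.19). Of the mitochondrially encoded protein genes, 0 of 13 tested rose and 13 fell (0 and 13 adjusted over the list alone), with a median of -0.84 and adjusted p = 6.57e-12 (adjusted p = 0.0813 with an estimated correlation). GABAergic and striatal neuron genes (16 up, 3 down of 25, median 0.65, adjusted p = 0.00200, adjusted p = 0.220 with an estimated correlation), cell cycle inhibitors (8 up, 2 down of 11, median 0.71, adjusted p = 0.00168, adjusted p = 0.123 with an estimated correlation), BMP and TGF-beta pathway genes (13 up, 3 down of 23, median 0.65, adjusted p = 0.0124, adjusted p = 0.0904 with an estimated correlation) and mesenchymal and endothelial markers (6 up, 0 down of 10, median 0.50, adjusted p = 0.0341, adjusted p = 0.524 with an estimated correlation) went up. WNT pathway genes (3 up, 11 down of 27, median -0.31, adjusted p = 0.0413, adjusted p = 0.201 with an estimated correlation) went down.

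Whether the doxycycline effect itself differed between times was tested as a difference of effects. Between 12 h and 24 h it differed upward for 3157 genes and downward for 2917. DUSP6 changed direction, from -2.62 ± 0.12 at 12 h to 2.66 ± 0.11 at 24 h, with a difference of 5.29 ± 0.16 (adjusted p = 3.72e-20). Its NoDox level was lower at 24 h than at 12 h, so both arms contributed to this difference. SELE (8.72 ± 1.05), CER1 (6.15 ± 0.54), the deiodinase DIO3 (4.68 ± 0.14) and the cadherin CDH6 (4.48 ± 0.19) differed upward. Beside GSX2 (-6.11 ± 0.30) and the transgene (-4.87 ± 1.30), FSTL5 (-3.82 ± 0.34), PCDH20 (-2.67 ± 0.79) and CACNA1I (-2.52 ± 0.34) differed downward. The effect differed upward for 16 of 21 FGF pathway genes tested and downward for 0 (16 and 2 adjusted over the list alone). Their median difference was 2.07, with camera adjusted p = 5.61e-16. Radial glia (18 up, 1 down of 22, median 1.11, adjusted p = 2.78e-16), Notch (15 up, 2 down of 21, median 0.90, adjusted p = 3.3e-09) and dorsal pallial lists (13 up, 1 down of 20, median 1.26, adjusted p = 1.12e-06) differed upward as well. With library totals only, the genes higher and lower were 1914 and 5719.

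Between 12 h and 48 h the effect differed upward for 3487 genes and downward for 3277, or 1700 and 6756 with library totals only. NXPH1 (4.81 ± 0.45), EDNRB (4.56 ± 0.17) and FZD5 (4.47 ± 0.23), beside SELE (6.66 ± 1.18) and CER1 (4.72 ± 0.88), differed upward. ALS2CL (-3.97 ± 0.36), NGEF (-3.30 ± 0.34) and CACNA1I (-3.16 ± 0.31) differed downward, beside the transgene (-10.11 ± 1.45) and GSX2 (-7.56 ± 0.35). G2 and M phase genes (0 up, 22 down of 23, median -0.52, adjusted p = 3.3e-11, adjusted p = 0.0996 with an estimated correlation) differed downward, and LGE progenitor regulators with GSX2 among them (12 up, 1 down of 14, median 1.81, adjusted p = 1.81e-09) and GABAergic and striatal neuron genes (17 up, 1 down of 25, median 1.25, adjusted p = 1.93e-06) upward.

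Between 24 h and 48 h the effect differed upward for 2491 genes and downward for 2573, or 1886 and 3190 with library totals only. PCDH20 (4.42 ± 0.54), CCSER1 (3.81 ± 0.32), FSTL5 (3.78 ± 0.29), GPR149 (3.70 ± 0.41) and ROBO2 (3.52 ± 0.16) differed upward. KDR (-4.31 ± 0.39), FAM181B (-3.31 ± 0.32), OLFML3 (-3.00 ± 0.37) and ISLR (-2.95 ± 0.40) differed downward, beside the transgene (-5.24 ± 1.22) and GSX2 (-1.45 ± 0.40). FGF pathway genes (1 up, 14 down of 21, median -0.65, adjusted p = 1.42e-09), neural crest markers (0 up, 5 down of 7, median -1.32, adjusted p = 0.00513, adjusted p = 0.0833 with an estimated correlation) and non-neural ectoderm and epithelial markers (0 up, 4 down of 8, median -0.66, adjusted p = 0.00682, adjusted p = 0.141 with an estimated correlation) differed downward.

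The genes that fell at 12 h shared more with those of 24 h than independent lists would. This benchmark ignores that calls varied with abundance. At 12 h, 1726 of 4879 genes above 50 CPM were lower, against 670 of 6850 of at most 5 CPM. For genes lower at 12 h an excess was also seen in the opposite direction, so an excess alone does not show that an effect persisted. Of the 3912 genes lower at 12 h, 1410 were lower at 24 h, where 660 would be shared by independent lists, and 760 were higher at 24 h against 667. Of the 3898 genes higher at 12 h, 1166 were higher at 24 h against 664, and 372 were lower against 658. By 48 h, 570 of the genes lower at 12 h were lower, against 349.7 for independent lists, and 596 were higher against 361. Of the genes higher at 12 h, 327 were higher at 48 h, against 359.8 for independent lists, but among genes at least 2-fold higher 31 were shared against 8. Between 24 h and 48 h, 607 genes were higher at both times against 309, and 631 lower at both against 296.

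Genes that rose or fell at least 2-fold as the uninduced cultures aged were tested as sets in the Dox effects. The 741 genes higher and 562 lower in NoDox 48 h were taken at 12 h and 24 h. The 307 genes higher and 110 lower in NoDox 24 h were taken at 12 h and 48 h. No set passed in camera (adjusted p from 0.0684 to 0.939). At an unadjusted p below 0.05 stood 2 sets: those higher by 24 h pointed down at 12 h, and those lower by 24 h pointed up. With an estimated correlation neither did (p = 0.291 and 0.1235, unadjusted).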

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

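The differences between times, the lists and the endothelial test were set before their results were seen; all other tests weighed here, and the counts of splits, were chosen after.

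The Dox effect differed between time points by a direct test of the difference. Between 12 h and 24 h it differed upward for 3157 genes and downward for 2917, and 1132 genes that passed at both times went opposite ways. Between 12 h and 48 h these numbers were 3487, 3277 and 940. Between 24 h and 48 h they were 2491, 2573 and 479. FGF pathway genes passed with opposite signs at 12 h and 24 h, and the difference passed (adjusted p = 5.61e-16). With the preset correlation this held also for BMP and TGF-beta pathway genes (adjusted p = 7.19e-07 for the difference) and hypoxia and glycolysis genes (adjusted p = 5.76e-06). With an estimated correlation neither list passed at 12 h (adjusted p = 0.0609 and 0.165) or at 24 h (adjusted p = 0.143 and 0.482), and the difference passed for the BMP list (adjusted p = 0.00125) and not for the hypoxia list (adjusted p = 0.0809).

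Other splits of the same libraries were counted for each comparison. For the 6 comparisons of 2 groups there are 10 splits, too few for a share under 0.05. The real split (1 of 10) called 7810, 6665 and 3571 genes for the Dox effects and 6253, 3402 and 8188 for the uninduced changes, each at 12, 24 and 48 h, against a highest other of 0. For the differences of the Dox effect, the 100 splits include the real one. For 24 h against 12 h, only the real split called as many as 6074 genes, 1 of 100 (highest other 4388). With the real split counted, it was 8 of 100 for 48 h against 12 h (real 6764, highest other 10353). For 48 h against 24 h it was 7 of 100 in the same way (real 5064, highest other 8701). These splits exchange libraries between time points, and the highest others kept the Dox libraries at their times and exchanged uninduced ones. They hold the change over time in each arm, a structure of the samples, and decide nothing about chance for any of the 3 differences.

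At 12 h, with TMM, genes of low abundance moved up and genes of high abundance moved down. Among genes with a mean of at most 5 CPM, 909 were higher and 434 lower by at least 2-fold, and above 50 CPM 5 were higher and 217 lower; without Dox 12 h replicate 3 these were 841 and 447, and 5 and 202. The direction of the abundant genes rested on the scaling: their median was -0.10 with TMM and 0.0836 with library totals only, where 7 were higher and 152 lower by at least 2-fold. No value decides between the scalings, so that direction stays open. The gap between the classes does not come from scaling, since 1 factor per library moves all genes alike: the median of genes of at most 5 CPM was 0.15 with TMM and 0.33 with library totals only. Background reads along the genome and doxycycline itself stay open too. The genes at least 2-fold higher gained 57.1 to 1888 times as much per kb as olfactory receptor genes, lowest in replicate 3, but they were chosen for their gain; receptor genes had 9.65 reads per M in that replicate against 3.26 and 3.30 in the other 2. No group separates the drug from the transgene. The mitochondrially encoded genes had a median log2 fold change of -0.0758. The ATF4 stress response list went up (camera adjusted p = 0.0306), a call lost with an estimated correlation. Neither value can be tied to the drug or to the transgene alone.

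Reads counted for GSX2 rose at 12 h of doxycycline. Reads of the transgene counted for GSX2 may account for this, since the ratio of GSX2 to transgene reads at 24 h minus that at 12 h was -0.0185, within the spread, although the transgene level fell. A rise of the resident gene stays open: 3.85% ± 15.1 of the GSX2 reads at 12 h lay beyond the ratio of 24 h.

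CER1, SELE and KDR rose at 24 h. For endothelial cells, the summed gain of 10 other endothelial genes was 30.5% ± 3.51 of the gain of KDR. This missed the bound written beforehand for excluding them and did not reach the gain that they would need, so they stay open. EGFL7 carried the gain, from 8.24 to 18.8 CPM, PLVAP rose from 0.283 to 0.875 CPM, and without EGFL7 the gain was 0.950%, a value chosen after the result and deciding nothing. CLDN5 went from 2.27 to 1.53 CPM, ESAM from 0.332 to 0.246, TEK from 2.26 to 2.54 and MMRN2 from 1.81 to 2.02, and EMCN had 0 reads in both groups, while KDR gained 35.9 CPM. Endoderm cells stay open as well. The summed gain of 5 endoderm genes was -3.26% ± 3.14 of that of CER1, far below what such cells would need. FOXA2 had 0 reads over all libraries, SOX17 and HHEX 4 each and GSC 58, and APELA, from 1.19 to 0.637 CPM, set the value. With 4 of the 5 genes near the floor, and the bound written after, this was not taken to exclude them. Of the lists fixed beforehand, mesoderm and endoderm markers did not pass at 24 h (camera adjusted p = 0.720). Mesenchymal and endothelial markers, which include KDR, did not either (camera adjusted p = 0.414). Members such as SOX17, FOXA1 and PECAM1 were too low to test, so these lists do not decide.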

How the results depend on the processing

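Library totals as the only scaling, and abundance without Dox 12 h replicate 3, were chosen after seeing the data; the other alternatives were planned. No named gene or list that passed was called in the opposite direction. With library totals only, 133 called genes for Dox 12 h and 140 for 48 h against 12 h changed sign, none of them called the other way. Of the counts of genes, 258 stayed within 1.5 times and 36 moved. The sets from the uninduced cultures passed in none of their 16 alternatives. Of the values of single genes and lists, 16236 kept their side of the threshold, 80 passed newly and 1426 no longer passed. Lists entered these totals only with an estimated correlation, fry and the replicate block, and not with library totals only.

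With library totals only, genes higher and lower were 7340 and 2213 (Dox 12 h), 1017 and 2835 (Dox 48 h), 1914 and 5719 (24 h against 12 h) and 1700 and 6756 (48 h against 12 h); no scaling factor is applied there, so the TMM factors make the difference. Tested against a log2 fold change of 1, they were 289 and 461, 224 and 293, and 8 and 20 for the Dox effects at 12, 24 and 48 h. The uninduced changes gave 33 and 9, 10 and 2, and 107 and 22. The differences gave 341 and 90, 374 and 174, and 125 and 64 for 24 h against 12 h, 48 h against 12 h and 48 h against 24 h. This test asks for a larger change by construction. At an absolute log2 fold change of at least 1, overlaps were 265 higher and 329 lower (12 and 24 h), 31 and 95 (12 and 48 h) and 65 and 115 (24 and 48 h), from fewer genes.

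Leaving out each replicate gave 1118 to 1567 higher and 945 to 1483 lower for the uninduced change to 24 h, lowest without NoDox 24 h replicate 1 and highest without Day 10 replicate 3. The Dox effect at 48 h gave 1041 (without NoDox 48 h replicate 2) to 1640 (without NoDox 48 h replicate 1) higher. The cause was not tested.

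For lists, the estimated correlation ended 68 calls and kept 211 results. The fry test, which sets a list against no change and not against the other genes, added 72 calls and ended 2. The replicate block added 8 and ended none. These were the mitochondrially encoded genes at Dox 24 h (adjusted p = 0.0424), radial glia (0.0225) and FGF pathway genes (0.0403) at Dox 48 h, dorsal pallial regulators at 24 h without doxycycline (0.0326), and 4 lists for 24 h against 12 h (0.0239 to 0.0395). Depth limits genes near the floor of 3 counts.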
